A study of Mus musculus with 6 samples.

How the data were processed

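Tumours of 6 KPC mice, 3 given vehicle and 3 given trametinib with hydroxychloroquine, were dissociated into single cells and profiled with 10x Genomics droplet libraries, 1 library per mouse. Per the labels, mice were enrolled when their tumours reached the set size by ultrasound and were assigned to a group at random. The deposited matrices hold raw UMI counts per gene and barcode, which the submitters' processing notes credit to Cell Ranger 5.0.1 and the mouse genome build mm10. The annotation release is not given in the sources used here. The matrices held 44819 barcodes already selected as cells, each with at least 500 UMIs, and 32285 features. Gene symbols and identifiers are those of the deposited feature lists, and coordinates were taken by identifier from GENCODE mouse M21 on mm10. Numbers 1 to 3 in the sample titles name different mice, and a check for pairing by number is given in the closing section.

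Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 39928. Scrublet's own threshold called between 0.0088% and 1.31% of a library's barcodes doublets, so a fixed share of 0.8% per 1000 barcodes with the highest scores was left out instead, 2926 in all, leaving 37002 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 31 clusters, with no integration across mice (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, matplotlib 3.10.9). Because the 31 clusters mixed cell types, each with at least 100 cells was divided again (1000 variable genes, 15 components, resolution 0.5), giving 198 sub-clusters. A sub-cluster of at least 20 cells took the name of 1 of 17 marker sets. A set was eligible with at least 3 markers at 50 CPM or more and at least 4-fold above the median sub-cluster (pseudocount 10 CPM). Among eligible sets, the name came from the 1 with the highest mean log2 fold of its markers over that median. Haemoglobin genes counted as markers only where they held 5% of a median cell's UMIs, and 12 stray red cells over 20% were removed from other classes. A sub-cluster was left unnamed by rule where its 10 leading genes held more markers of another type than of its own. The same held where its UMI count was low for its library and those genes held no marker of its own type. These rules were not in the plan fixed in advance. Where the leading genes otherwise pointed to a different type, or to several types, the sub-cluster was left unnamed by hand. The division into sub-clusters, the haemoglobin rule and the hand review were decided after the clusters were seen and before any gene was tested. In all, 11 sub-clusters and 1124 cells (3.04%) stayed unnamed, from 0.42% of cells in vehicle 1 to 9.74% in treated 2. The tumour and ductal epithelial class rests on markers, and no mutation was read in single cells.

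Counts were summed per mouse and class over mice with at least 20 cells, and 7 classes were tested in all 6 mice. Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit and test) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes of a class at 0.05. Fold changes are on the log2 scale, treated over vehicle, and CPM are UMI counts scaled to the total of the class in that mouse. Before the data were examined, 37 gene lists, 17 marker sets, the tests, the alternatives and the genes to be named were fixed. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 216 tests of 35 lists with at least 5 measured genes, and repeated with the correlation estimated from the data and with fry, whose directional test asks whether a list's genes move 1 way without comparing them with other genes. Calls at the preset correlation take genes of a list as nearly independent, and each is given with its value at the estimated one. Cell shares were compared by a two-sided exact permutation test over the 10 splits of 6 mice, with a smallest p of 0.1. Cell numbers of 14 classes with at least 60 cells were tested in edgeR with the total of kept cells as library size. Differences in response between tumour cells and fibroblasts or macrophages were tested on the 12 sums of each pair of classes, with terms for mouse, class and class by treatment.

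Named genes follow a fixed rule. In each class it takes, among genes past the threshold with an absolute log2 fold change of at least 1, an average log2 CPM of at least 5 and no overlap between groups, the 10 largest rises and 10 largest falls, leaving unnamed predicted, ribosomal, mitochondrial, sex-linked and receptor genes and markers of another class. It adds up to 4 members of each list named in the text that passed, or the 2 most abundant where none did, 8 genes chosen for every class, and up to 8 genes per pair of classes. Genes outside it are said to be chosen after their values were seen.

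Alternatives were DESeq2 1.42.0, another scaling, no filter on low counts, the replicate number as a block, doublets kept, at most 10% mitochondrial UMIs, at least 500 genes per cell, at least 50 cells per mouse, a filter against free RNA that drops genes under 10% of their level in another class, and leaving out each mouse. Summing treated 1 and 2, leaving out vehicle 1 and treated 2 together, using only tumour clusters present in every mouse, and leaving out mice in the test of differences in response were added after seeing the data. Each test was also run on the 9 other splits of the mice. Sensitivity was tested on counts drawn anew from the mean and fitted spread of each gene, with the mice drawn independently. In these draws 200 genes were raised or lowered 2-fold or 4-fold in the treated mice. RNA of tumour origin in other classes was estimated from 16 epithelial markers. Likeness of mice was measured as the robust SD of log2 ratios over genes at 50 CPM or more, for 15 pairs of mice. Depth per class and mouse, given in the text, sets the precision of each value, and counting intervals are exact at 95%.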

Results

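Droplet single-cell RNA sequencing measured gene expression in pancreatic tumours of KPC mice, a genetically engineered model of pancreatic ductal adenocarcinoma. Tumours of 3 mice given vehicle were compared with tumours of 3 mice given trametinib (1 mg/kg), an inhibitor of the kinase MEK, together with hydroxychloroquine (40 mg/kg), which raises the pH of lysosomes and blocks the last step of autophagy. All tumours measured 4 to 7 mm by ultrasound at enrolment and were taken 24 h after treatment. Vehicle libraries 1, 2 and 3 held 22996012, 122040812 and 126645602 UMIs, of which 2144, 9469 and 10304 cells were kept. Treated libraries 1, 2 and 3 held 70523616, 76593524 and 103825578 UMIs and gave 3941, 5153 and 5991 cells. Median depth differed between the groups, with 2996 to 4701 UMIs per kept cell in vehicle mice and 8384 to 11182 in treated mice. Barcodes with over 20% mitochondrial UMIs made up 3.86% to 8.19% of vehicle libraries and 7.76% to 19.8% of treated libraries. Vehicle 1 stood apart in its cell barcodes: 25.9% of them shared their leading 7 bases with vehicle 2, against 99.8% to 100% for each pair among the other 5 libraries. A library set of 1 vehicle mouse allows no comparison within it, so results that changed without vehicle 1 are given with that value. Treated 1 and treated 2 were closer to each other than any other pair of mice in each of 4 classes compared; in tumour cells the spread of their log2 ratios was 0.12, against 0.50 to 0.86 for the other 14 pairs. Vehicle 2 was the only mouse with male-type expression, with the Y-linked helicase Ddx3y at 27.3 CPM (UMI counts scaled to the library total). All p-values rest on the mice as the labels give them.

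The question for the cell classes was whether the drug combination changed the make-up of the tumour within 24 h. Tumour and ductal epithelial cells made up 35.8% ± 19.3 (SD, n = 3) of kept cells in treated mice and 34.2% ± 7.17 in vehicle mice. Macrophages and monocytes took 28.0% ± 12.6 and 23.2% ± 7.02, and fibroblasts 7.47% ± 1.86 and 8.79% ± 5.13. Neutrophils held 9.53% ± 4.59 of treated and 19.4% ± 8.71 of vehicle cells, but 9.97% and 12.3% among cells with at least 500 genes (exact p = 0.7). Mesothelial cells, which line the abdominal cavity, were found as 19, 14 and 47 cells in treated 1, 2 and 3 and as 0, 1 and 0 in the vehicle mice, a ratio of shares of 116 with an exact 95% counting interval of 20.3 to 4648. Islet endocrine cells numbered 19, 90 and 22 in treated mice and 1, 14 and 3 in vehicle mice, a ratio of 10.6 with an exact 95% interval of 6.44 to 18.4. These intervals cover counting error only.

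A model of cell numbers in edgeR called both classes higher among 14 tested: mesothelial cells by a log2 fold change of 6.31 ± 1.08 (SE, adjusted p = 0.0042) and islet cells by 3.44 ± 0.97 (adjusted p = 0.0483). The islet call was lost without treated 2 (2.41, adjusted p = 0.183), without vehicle 1 (3.27, adjusted p = 0.118), without vehicle 3 (2.97, adjusted p = 0.0989), with doublets kept (3.60, adjusted p = 0.0625) and with TMM scaling (3.74, adjusted p = 0.104), and it stood at 4.56 without vehicle 2. With doublets kept, vehicle 2 and vehicle 3 held 7 and 14 mesothelial cells and the mesothelial call was lost (log2 fold change 2.86, adjusted p = 0.0880). It was also lost with the replicate number as a block (adjusted p = 0.0791), although the numbers showed no clear pairing of the mice. Shares were also compared by a two-sided exact permutation test, whose smallest p is 0.1 with 3 against 3 mice. This exact test gave p = 1 for tumour cells, p = 0.7 for macrophages, p = 0.9 for fibroblasts, p = 0.2 for neutrophils and p = 0.1 for mesothelial and islet cells. Endothelial cells (4.26% ± 1.40 against 2.75% ± 0.767, exact p = 0.2), T and NK lymphocytes (3.61% ± 2.22 against 2.43% ± 0.527, exact p = 0.6) and B lymphocytes (2.48% ± 3.42 against 4.10% ± 3.79, exact p = 0.5) overlapped between the groups. Conventional dendritic cells stood at 0.344% ± 0.0566 and 1.16% ± 0.688 (exact p = 0.2). Among immune cells alone, macrophages made up 61.2%, 71.4% and 59.7% in treated mice and 41.8%, 43.2% and 49.2% in vehicle mice (exact p = 0.1), while the neutrophil shares of 21.7% ± 5.55 and 36.4% ± 10.4 gave an exact p = 0.2.

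**Figure D1:**
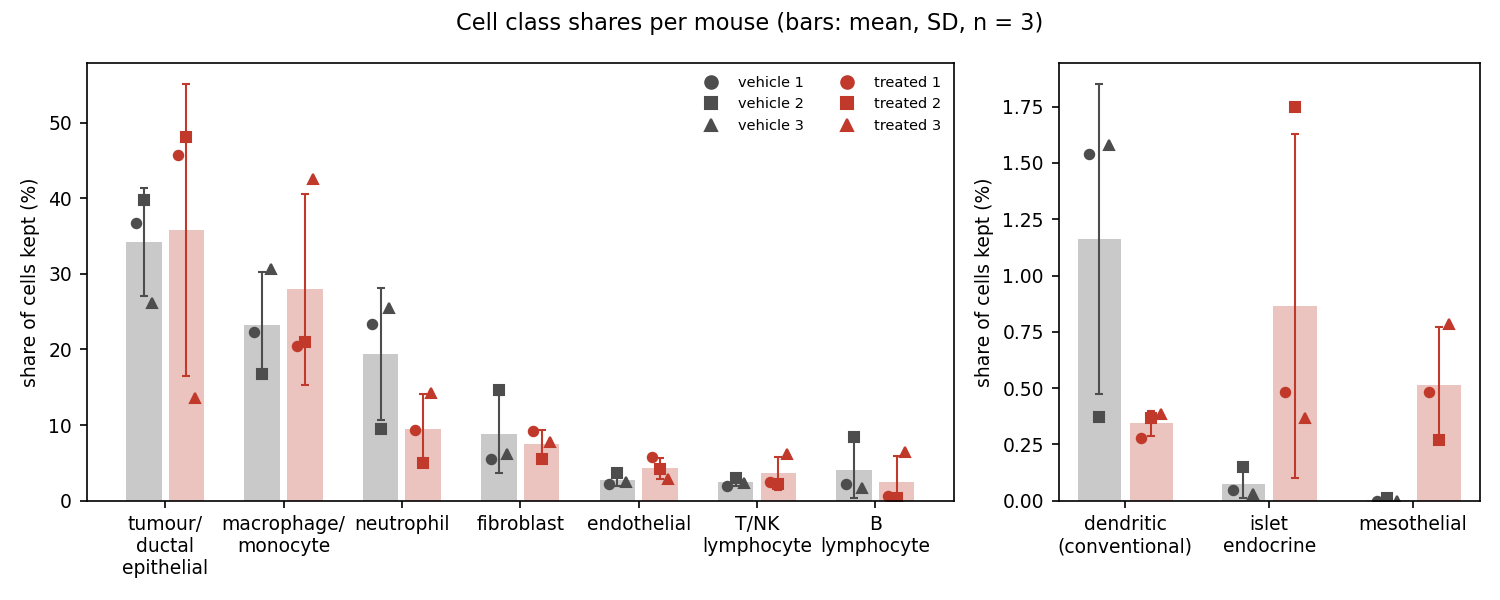
Share of kept cells (%) per cell class for each mouse, with grey for vehicle and red for treated; bars are means with SD (n = 3), and the right panel has its own scale. Mesothelial cells are seen in all 3 treated mice, at 0.513% ± 0.258 on average, and neutrophil shares of the groups overlap.

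The comparison of tumour cells asked what the combination did to the epithelial cells of the tumour. Among read-outs of MEK signalling, Dusp6, a phosphatase that ERK induces as its own brake, stood at 60.5 ± 3.85 CPM in treated and 66.7 ± 18.2 CPM in vehicle mice (SD, n = 3). The feedback inhibitor Spry4 stood at 8.90 and 10.5 CPM, the ETS factor Etv4 at 30.3 ± 0.605 and 36.9 ± 16.1 CPM, and its relative Etv5 at 30.1 ± 3.16 and 18.9 ± 4.00 CPM. Etv5 was thus higher in every treated mouse, with a log2 fold change of 0.67 that missed the threshold (adjusted p = 0.402). For autophagy and lysosomes, the cargo receptor Sqstm1 stood at 71.2 ± 6.20 and 103 ± 22.8 CPM, the autophagosome protein Map1lc3b at 337 ± 13.8 and 358 ± 41.0 CPM, and the lysosomal protease Ctsd at 281 ± 190 and 375 ± 158 CPM. Hmgcs1, an early enzyme of cholesterol synthesis, stood at 40.1 ± 4.45 and 67.3 ± 34.7 CPM.

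Over all classes these 8 genes, chosen in advance, gave 41 tests, of which 1 passed, Etv4 in endothelial cells. None passed in tumour cells; their log2 fold changes and adjusted p were −0.14 and 0.843 for Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489), −0.24 and 0.784 for Spry4 (ENSMUSG00000024427, chromosome 18, 38586247 to 38601415), and −0.28 and 0.743 for Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371). They were −0.53 and 0.449 for Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827), −0.09 and 0.884 for Map1lc3b (ENSMUSG00000031812, chromosome 8, 121590361 to 121598760), −0.42 and 0.771 for Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038), and −0.75 and 0.526 for Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260). Etv5 is ENSMUSG00000013089 (chromosome 16, 22381309 to 22439719). Of 15518 genes tested in tumour cells, edgeR called 0 changed, with 1866 at an unadjusted p under 0.05, and DESeq2 called 447. Sums per mouse held 14399143 to 83541558 UMIs from 788 to 3759 cells. Changes of 4-fold, simulated with the mean and spread of these tumour sums, were recovered in 0% of genes. A change of that size was thus not detectable against the spread between the sums of the mice. That spread may include unlike cells within the class. A sub-cluster led by genes of intestinal epithelium, with cells of vehicle 1, was kept in it, as given in the closing section. How much this adds to the spread was not tested. The groups did not overlap for 19.8% of genes, where chance gives 10% if the mice are independent. Treated 1 and 2 were closer to each other in tumour cells than any other pair. Such likeness raises the share expected by chance, so 19.8% may not lie above it. The largest cluster of tumour cells differed between mice: it was cluster 25 in treated 1 and 2 (64.1% and 68.8%), 11 in treated 3 (54.8%), 9 in vehicle 1 (92.6%), 18 in vehicle 2 (37.3%) and 26 in vehicle 3 (83.4%).

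**Figure D2:**
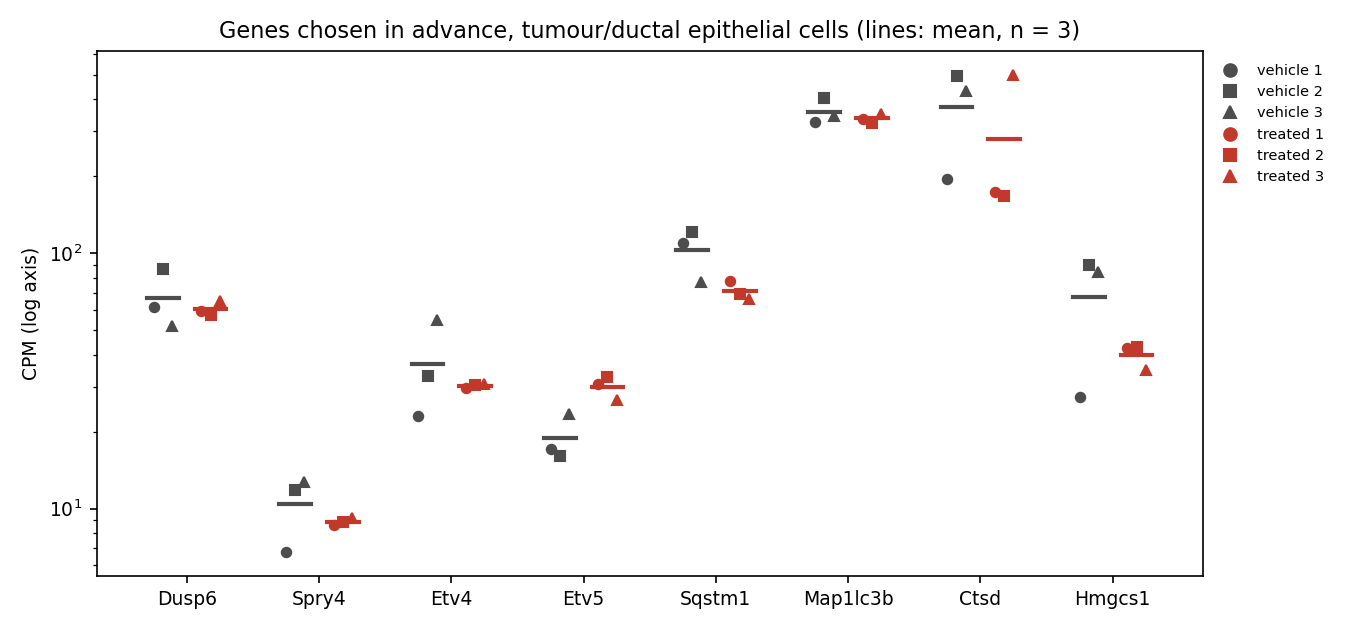
Expression (CPM, log axis) of the 8 genes chosen in advance, in tumour and ductal epithelial cells; points are mice, grey for vehicle and red for treated, and lines are means (n = 3). Dusp6 and Map1lc3b overlap between the groups, and Etv5 lies higher in all 3 treated mice.

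Camera called metabolic and antigen-presentation lists lower in tumour cells, calls that were lost with an estimated correlation. All 24 measured genes of cholesterol synthesis had a negative log2 fold change, with a median of −1.04 (camera adjusted p = 8.9e-10; adjusted p = 0.601 with an estimated correlation); 0 of them fell by the gene test and 10 did when adjusted over the list alone. Fdps and Ebp, enzymes of that pathway, stood at −1.38 and −1.15 (adjusted p = 0.398 for each). The 14 genes of MHC class II presentation had a median of −1.61 (adjusted p = 4.3e-07; adjusted p = 0.601 with an estimated correlation), with the invariant chain Cd74 at −1.55 (adjusted p = 0.398), and 0 passed either over all genes or adjusted over the list alone. A filter on genes under 10% of their level in another cell class left too few of these to test, and the median was −2.48 without treated 3. Tumour cells of the 3 treated mice all lay below those of the 3 vehicle mice for both lists. For cholesterol synthesis 3 of the 10 splits of the mice, the real one included, gave as small a camera p. For MHC class II only the real split did. Oxidative phosphorylation (30 genes, median −0.54, adjusted p = 8.5e-07) and ribosomal protein genes (91 genes, median −0.89, adjusted p = 1.9e-18) were lower too, each with adjusted p = 0.601 with an estimated correlation and 0 members past the test, also adjusted over the list alone; the ribosomal median was −0.57 without vehicle 3. Genes of G2 and mitosis had a median of −0.48 (adjusted p = 0.0009; adjusted p = 0.717 with an estimated correlation; 0 members adjusted over the list alone), a call lost without treated 3 (−0.29, adjusted p = 0.0516) and without vehicle 3 (−0.04, adjusted p = 0.438). The 25 MAPK output genes had a median of −0.26 (adjusted p = 0.464; 7 above and 18 below 0), which passed without vehicle 1 (−0.48, adjusted p = 0.00152, in a range of 0.00152 to 0.964 over the mice left out) and was −0.12 without vehicle 2 or vehicle 3. Of these, Ccnd1, the cyclin of G1, stood at −0.26 (adjusted p = 0.716) and Ier3 at −1.47 (adjusted p = 0.417). The 39 lysosome genes had a median of −0.26 (adjusted p = 0.36), which passed without vehicle 3 (−0.35, adjusted p = 0.00157) and was −0.13, −0.10, −0.11 and −0.05 without treated 1, treated 2, vehicle 1 and vehicle 2. The 34 autophagy genes had a median of −0.13 (adjusted p = 0.514), which was −0.03 without vehicle 2, −0.08 without treated 2 or vehicle 1 and −0.24 without treated 3.

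Endothelial cells had 152 genes changed in edgeR, and cell cycle genes were among the falls. Cks2, a partner of cyclin-dependent kinases, fell 7.5-fold, from 98.3 ± 26.2 CPM in vehicle to 13.9 ± 3.01 CPM in treated mice (SD, n = 3). Cdk1, the kinase of mitotic entry, fell 6.6-fold, from 68.7 ± 40.3 to 11.8 ± 5.66 CPM, and Mcm5, a part of the replicative helicase, fell 7.21-fold, from 40.0 ± 5.95 to 5.64 ± 1.70 CPM. Ptprb, a phosphatase of the vessel wall, rose from 454 ± 73.0 to 975 ± 86.6 CPM, and Abca1, which exports cholesterol, rose from 160 ± 5.05 to 333 ± 27.3 CPM. The ERK-responsive factor Etv4 fell from 24.4 ± 15.1 to 4.03 ± 1.91 CPM, while Dusp6 (log2 fold change 0.53, adjusted p = 0.204) and Spry4 (−0.26) did not pass.

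Of 10127 genes tested in endothelial cells, edgeR called 23 higher and 129 lower, with 2064 at an unadjusted p under 0.05, and DESeq2 called 203. The sums came from 47 to 343 cells and 160317 to 2595107 UMIs per mouse. For 27.2% of genes the groups did not overlap, where chance gives 10% if the mice are independent. The likeness of treated 1 and 2 raises that chance value here too, by an amount that was not tested. The count of 152 rested on few mice. It was 2 without treated 1, 4 without treated 2, 821 without vehicle 1 (the mouse with 47 cells), 325 without vehicle 2, 38 without vehicle 3, and 2 with treated 1 and 2 summed as 1 sample, an alternative added after seeing the data. The fixed rule named 20 genes, of which 19 passed in DESeq2. Cks2 alone among them passed without each mouse in turn and with treated 1 and 2 summed; Mcm5, a list member, also passed both (highest adjusted p 0.0464 and 0.0218).

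The 10 genes named for the largest falls in endothelial cells were led by Cks2 (ENSMUSG00000062248, chromosome 13, 51645232 to 51650660; log2 fold change −2.91 ± 0.25 SE, adjusted p = 0.00125) and Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938; −2.72 ± 0.39, adjusted p = 0.0116). Hmgb2, a chromatin protein of dividing cells, fell by 1.99 on the log2 scale (adjusted p = 0.00982), the nucleoside diphosphate kinase Nme1 by 1.89 (adjusted p = 0.0113) and the nucleotide pyrophosphatase Dctpp1 by 2.06 (adjusted p = 0.00982). Tuba1c, a tubulin whose reads can be shared with near-identical copies, fell by 1.92 (adjusted p = 0.0109). The other 4 were Plac8 (−2.01, adjusted p = 0.0466), the protease inhibitor Timp1 (−1.97, adjusted p = 0.0255), and the MHC class II genes H2-Aa (−2.00, adjusted p = 0.00982) and Cd74 (−1.84, adjusted p = 0.0333); all 4 were removed by the filter on genes under 10% of their level in another class, and Cd74 stood at 0.085 with doublets kept (adjusted p = 0.989). Among the 10 rises, the non-coding AY036118 (ENSMUSG00000105361, chromosome 17, 39847113 to 39848035) had the largest, from 120 ± 39.1 to 663 ± 199 CPM (2.37 ± 0.31, adjusted p = 0.00982). C1qtnf9 (2.21, adjusted p = 0.0379), Pgm5 (1.79, adjusted p = 0.0433), the TGF-beta binding protein Ltbp1 (1.73, adjusted p = 0.0488), Limch1 (1.48, adjusted p = 0.00982), the transcription factor Klf9 (1.09, adjusted p = 0.027), Dock9 (1.08, adjusted p = 0.0498) and the mitochondrial kinase Pink1 (1.01, adjusted p = 0.0395) followed. Ptprb rose by 1.09 and Abca1 by 1.07 (adjusted p = 0.0419 and 0.0273).

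**Figure D3:**
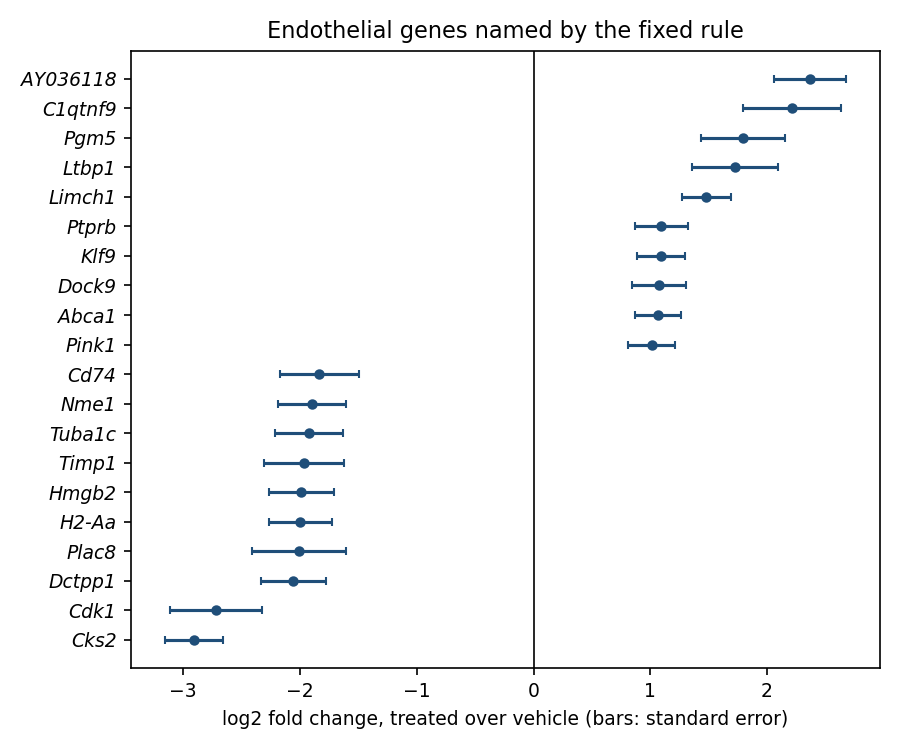
Log2 fold change (treated over vehicle) of the 20 endothelial genes named by the fixed rule; points are edgeR estimates and bars are standard errors (n = 3 per group). Cks2 and Cdk1 have the largest falls and AY036118 the largest rise.

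By group, 13 of 25 endothelial S-phase genes fell (22 adjusted over the list alone; median −1.45, camera adjusted p = 9.8e-25; adjusted p = 0.488 with an estimated correlation). The replication genes Mcm5 (−2.85, adjusted p = 0.00282), Mcm6 (−2.52, adjusted p = 0.00982), Prim1 (−2.55, adjusted p = 0.0200) and Rrm2 (−3.02, adjusted p = 0.0488) were among them. Of 17 genes of G2 and mitosis, 8 fell (17 adjusted over the list alone; median −3.42, adjusted p = 1.2e-18; adjusted p = 0.601 with an estimated correlation), including Ccnb2 (−3.64, adjusted p = 0.00982), a cyclin of mitosis, and the kinase Aurka (−3.47, adjusted p = 0.00996). Both lists overlapped between the groups, with vehicle 1 near the treated mice. In MHC class II presentation 4 of 8 genes fell (7 adjusted over the list alone; median −1.81, adjusted p = 1.3e-09; adjusted p = 0.488 with an estimated correlation), among them H2-Ab1 (−1.90) and H2-Eb1 (−1.79). Markers of other cells moved too: the tumour marker Tff1 fell in endothelial cells (−3.92, adjusted p = 0.0148), and RNA of tumour origin was estimated at 2.32% to 8.33% of endothelial UMIs in treated and 4.45% to 5.14% in vehicle mice. Of 30 genes of oxidative phosphorylation 2 fell, Cycs (−1.24, adjusted p = 0.0139) and Atp5g1 (−1.02, adjusted p = 0.0488), and 10 did when adjusted over the list alone (median −0.53, adjusted p = 1.3e-09; adjusted p = 0.488 with an estimated correlation). Of 25 Myc target genes 2 fell, Srm (−1.52, adjusted p = 0.019) and Fbl (−0.98, adjusted p = 0.0401), and 8 did when adjusted over the list alone (median −0.68, and −0.42 without vehicle 3; adjusted p = 2.2e-06; adjusted p = 0.669 with an estimated correlation). Ribosomal protein genes had a median of −0.72 (89 genes, 0 past the test, 56 adjusted over the list alone; adjusted p = 1.2e-18; adjusted p = 0.601 with an estimated correlation). The Etv4 call (log2 fold change −2.72, adjusted p = 0.0193) was lost without treated 1 (adjusted p = 0.0855), treated 2 (adjusted p = 0.0773) or vehicle 3 (adjusted p = 0.140).

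In macrophages and monocytes camera called the lysosome list higher and the mitotic list lower after treatment, calls that were lost with an estimated correlation. All 32 measured genes of G2 and mitosis had negative log2 fold changes, with a median of −1.83, and 35 of 39 lysosome genes had positive ones, with a median of 0.55. The lysosomal protease Ctsd stood at 3110 ± 789 CPM in treated and 999 ± 236 CPM in vehicle mice (SD, n = 3), and Psap, the precursor of the saposins that help lysosomes break down lipids, at 4236 ± 565 and 1885 ± 583 CPM. Top2a, the topoisomerase of dividing cells, stood at 19.9 ± 6.91 and 80.2 ± 19.9 CPM. None of these 3 genes passed over all genes, with adjusted p = 0.116, 0.205 and 0.0835. The mitotic list shifted with camera adjusted p = 5.3e-55 (adjusted p = 0.395 with an estimated correlation) and 28 of its 32 genes fell when adjusted over the list alone. The lysosome list shifted with adjusted p = 2.4e-14 (adjusted p = 0.395 with an estimated correlation) and 12 of its genes rose when adjusted over the list alone. Genes of alternatively activated macrophages had a median of 0.46 (20 genes, 3 risen adjusted over the list alone; adjusted p = 2.1e-05; adjusted p = 0.395 with an estimated correlation). The median was 0.75 without treated 2, 0.69 without vehicle 1 and 0.99 without vehicle 3. Its most abundant members were uneven, with the chitinase-like Chil3 at 3.29 (adjusted p = 0.461) and fibronectin, Fn1, at 0.45 (adjusted p = 0.801). For all 3 lists the treated mice lay wholly on 1 side of the vehicle mice.

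Of 11552 genes tested in macrophages, edgeR called 0 changed, with 1217 at an unadjusted p under 0.05, and DESeq2 called 307; simulated 4-fold changes were recovered in 74.7% of genes. Genes singled out after their values were seen had adjusted p = 0.0727 each. Plac8 stood at 56.8 ± 13.7 CPM in treated and 380 ± 46.1 CPM in vehicle mice (log2 fold change −2.74 ± 0.26 SE), and Ly6a at −3.62 ± 0.45. Lpl, which releases fatty acids from lipoproteins, stood at 351 ± 251 and 19.2 ± 5.46 CPM (4.21 ± 0.55). The fatty acid binding protein Fabp4 stood at 4.18 ± 0.53, the monoacylglycerol lipase Mgll at 3.71 ± 0.41, and Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, at 3.42 ± 0.45. The largest macrophage cluster was cluster 7 in treated 1 and 2, cluster 2 in treated 3, cluster 8 in vehicle 1 and cluster 1 in vehicle 2 and 3. RNA of tumour origin was estimated at 1.15% to 1.88% of macrophage UMIs in treated and 3.08% to 7.15% in vehicle mice. The classical tumour programme, epithelial genes such as Ctse (−0.54) and Tff2 (−0.36), had a median of −1.49 in macrophages (13 genes, 2 fallen adjusted over the list alone; adjusted p = 0.0013; adjusted p = 0.665 with an estimated correlation), a call lost without vehicle 2 (−0.06, adjusted p = 0.227). S-phase genes (median −0.56, adjusted p = 2.5e-05; adjusted p = 0.694 with an estimated correlation) lost their call without treated 3 (−0.19, adjusted p = 0.123) and had a median of −0.87 without treated 2. Autophagy genes (median 0.23, adjusted p = 0.0312; adjusted p = 0.601 with an estimated correlation) lost theirs without treated 3 (adjusted p = 0.125), vehicle 1 (adjusted p = 0.0638) or vehicle 2 (adjusted p = 0.0534). Neither list had members past the test adjusted over the list alone. Ribosomal protein genes had a median of −0.53 (90 genes; adjusted p = 1.9e-10; adjusted p = 0.694 with an estimated correlation; 0 adjusted over the list alone), which was −0.18 without vehicle 1.

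**Figure D4:**
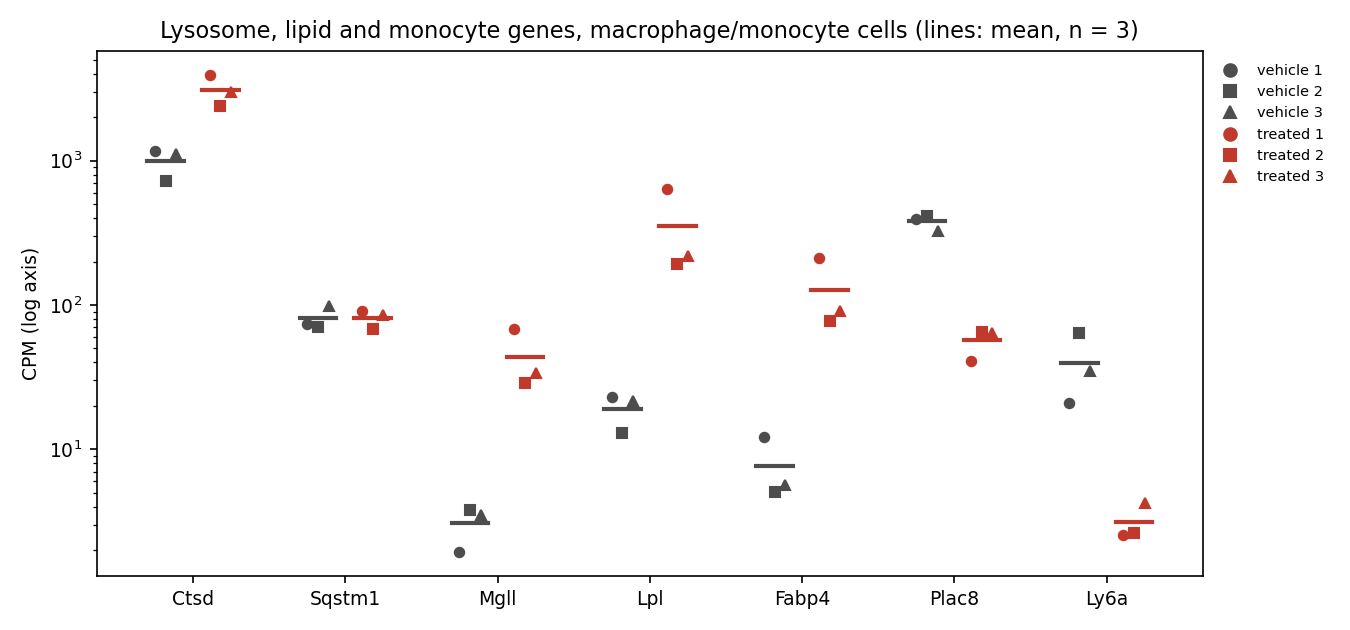
Expression (CPM, log axis) of 7 genes in macrophages and monocytes; points are mice, grey for vehicle and red for treated, and lines are means (n = 3). Ctsd and Sqstm1 were chosen in advance and the other 5 after their values were seen; Sqstm1 overlaps between the groups, and Ctsd is higher in each treated mouse.

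Cell cycle genes were uneven among the vehicle mice in fibroblasts. S-phase and mitotic genes together summed to 574, 386 and 799 CPM in fibroblasts of treated 1, 2 and 3, and to 304, 1911 and 1651 CPM in vehicle 1, 2 and 3. In endothelial cells the sums were 507, 377 and 603 against 543, 2891 and 2243 CPM, and in macrophages 839, 845 and 529 against 1011, 1807 and 1415 CPM. Vehicle 1 lay below all treated mice in fibroblasts and among them in endothelial cells. The fibroblast medians were −2.04 for the mitotic list (adjusted p = 5.6e-12; adjusted p = 0.665 with an estimated correlation) and −0.90 for the S-phase list (adjusted p = 8.7e-06; adjusted p = 0.694 with an estimated correlation), with 0 members past the test adjusted over the list alone.

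**Figure D5:**
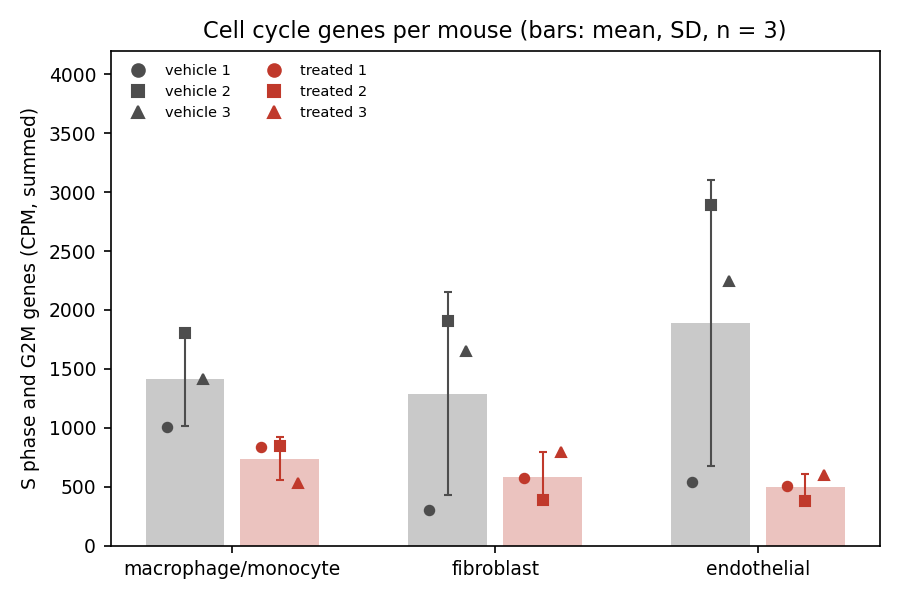
Summed expression (CPM) of S-phase and G2M genes in 3 cell classes for each mouse, grey for vehicle and red for treated; bars are means with SD (n = 3). All 3 treated mice lie below all 3 vehicle mice in macrophages, while vehicle 1 lies below the treated mice in fibroblasts and among them in endothelial cells.

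Genes of MHC class I presentation were higher as a group in fibroblasts, with 16 of 19 above 0 and a median of 0.51 (adjusted p = 0.0012; adjusted p = 0.488 with an estimated correlation; 5 risen adjusted over the list alone). Its most abundant members went the other way, B2m, the light chain of class I molecules, at −0.20 (adjusted p = 0.859) and the chaperone Calr at −0.55 (adjusted p = 0.307). Myc target genes had a median of −0.47 (25 genes, 8 fallen adjusted over the list alone; adjusted p = 2.6e-07; adjusted p = 0.601 with an estimated correlation), with the nucleolar proteins Npm1 at −0.32 and Ncl at −0.07. Oxidative phosphorylation (30 genes, median −0.54, 2 fallen adjusted over the list alone; adjusted p = 2.7e-08; adjusted p = 0.548 with an estimated correlation) and ribosomal protein genes (88 genes, median −0.55, 0 adjusted over the list alone; adjusted p = 8.7e-13; adjusted p = 0.665 with an estimated correlation) were lower as well, with medians of −0.30 and −0.35 without vehicle 1. MAPK output genes had a median of −0.47 in fibroblasts (25 genes, 22 below 0, 0 adjusted over the list alone; adjusted p = 0.0087; adjusted p = 0.601 with an estimated correlation). Dusp6 stood at 23.3 ± 3.91 and 35.5 ± 3.13 CPM (log2 fold change −0.59, adjusted p = 0.24), Etv4 at −1.15 (adjusted p = 0.278), and the abundant members Emp1 and Ier3 at −0.55 and −0.08. Of 12477 genes tested in fibroblasts, edgeR called 0 changed, with 1982 at an unadjusted p under 0.05, and DESeq2 called 320; simulated 4-fold changes were recovered in 69.8% of genes. The edgeR count was 9 without vehicle 1 and 1 without treated 3. Cluster 21 was the largest for fibroblasts of treated 1 and 2, cluster 6 for treated 3, vehicle 1 and vehicle 3, and cluster 30 for vehicle 2. RNA of tumour origin was estimated at 2.16% to 3.66% of their UMIs in treated and 3.44% to 5.95% in vehicle mice.

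In T and NK lymphocytes the transcripts that fell were far more abundant in other cells of the tumour. Il1b, an inflammatory cytokine of myeloid cells, fell 15.1-fold, from 144 ± 17 to 9.65 ± 2.45 CPM (SD, n = 3), and the neutrophil-attracting chemokine Cxcl2 fell from 285 ± 162 to 28.3 ± 19.7 CPM. The keratin Krt7, a ductal marker, fell from a mean of 47.6 to 0.968 CPM. Neb, which encodes nebulin, rose from 32.1 ± 10.4 to 130 ± 49.5 CPM. Of 5054 genes tested, edgeR called 1 higher and 6 lower, with 193 at an unadjusted p under 0.05, and DESeq2 called 12. The rule named Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139; log2 fold change −3.92 ± 0.36 SE, adjusted p = 1.97e-05), Ifitm1 (−4.47, adjusted p = 0.0111), Cxcl2 (−3.16, adjusted p = 0.0272), H2-Eb1 (−2.46, adjusted p = 0.0403) and Neb (2.13, adjusted p = 0.0403). Krt7 (−4.35, adjusted p = 0.0125) and Timp1 (−2.84, adjusted p = 0.0403) were chosen after their values were seen. The filter on genes under 10% of their level in another class removed all 6 genes that fell and left 0 calls, with Neb at adjusted p = 0.14. The count of 7 was 3 without treated 1, 1 without treated 2, 11 without treated 3, 30 without vehicle 1, 4 without vehicle 2, 13 without vehicle 3, and 4 with treated 1 and 2 summed; Il1b passed without each mouse in turn, and the other 4 genes the rule named did not (highest adjusted p from 0.0598 for Ifitm1 to 0.51 for Cxcl2). Sums held 70789 to 1436366 UMIs from 42 to 370 cells.

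By group, T and NK lymphocytes had a median of −1.96 for MHC class II presentation (7 genes, 1 fallen, 5 adjusted over the list alone; adjusted p = 4.9e-11; adjusted p = 0.395 with an estimated correlation) and −0.45 for NF-kB and inflammatory cytokines (14 genes, 2 fallen, 3 adjusted over the list alone; adjusted p = 8.1e-09; adjusted p = 0.488 with an estimated correlation). The cytokine median was −0.26 without treated 2 and −0.69 without treated 3. With the filter on genes of other classes that list was no longer called (adjusted p = 0.177). The same filter removed H2-Eb1, the 1 class II gene that fell, and left 5 lists called in this class, against 11 without it. Ribosomal protein genes had a median of −0.33 (0 of 85 adjusted over the list alone; adjusted p = 8.2e-09; adjusted p = 0.694 with an estimated correlation), lost without vehicle 1 (−0.11, adjusted p = 0.175).

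In neutrophils and B lymphocytes camera called the ribosomal protein list lower, calls that were lost with an estimated correlation. In neutrophils the medians were −1.44 for ribosomal protein genes (86 genes; adjusted p = 7.7e-21; adjusted p = 0.665 with an estimated correlation) and −1.35 for Myc targets (20 genes, all below 0; adjusted p = 2.9e-10; adjusted p = 0.601 with an estimated correlation). Without vehicle 1 they were −0.30 and −0.57. Neutrophil MAPK output genes had a median of −0.60 (15 genes; adjusted p = 0.0432; adjusted p = 0.694 with an estimated correlation), lost without treated 1 (adjusted p = 0.141), treated 2 (adjusted p = 0.0854) or vehicle 2 (adjusted p = 0.544) and at 0.28 without vehicle 3 (adjusted p = 0.899) and −0.91 without vehicle 1. The neutrophil lysosome list had a median of 0.14 (34 genes; adjusted p = 0.0343; adjusted p = 0.694 with an estimated correlation), lost without treated 1 (adjusted p = 0.121), treated 2 (adjusted p = 0.0692) or vehicle 1 (−0.01, adjusted p = 0.738); it was 0.07 without treated 3 and 0.29 without vehicle 3. In B lymphocytes ribosomal protein genes had a median of −0.32 (78 genes, and −0.18 without vehicle 1; adjusted p = 2.3e-09; adjusted p = 0.659 with an estimated correlation) and mitochondrially encoded genes a median of 0.51 (12 genes; adjusted p = 0.00021; adjusted p = 0.601 with an estimated correlation). None of these 6 lists had members past the test adjusted over the list alone. Of 7724 neutrophil and 1922 B-cell genes tested, edgeR called 0 changed in each, with 408 and 49 at an unadjusted p under 0.05, and DESeq2 called 2 in each. Without vehicle 1, edgeR called 2 neutrophil and 9 B-cell genes. The largest neutrophil cluster was cluster 4 in the treated mice and vehicle 2, cluster 3 in vehicle 1 and cluster 5 in vehicle 3. Of genes changed 4-fold in the simulation, 0% were recovered in neutrophils and 98.8% in B lymphocytes. The changed genes were a larger share of those tested in B lymphocytes, so these 2 values cannot be compared.

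Over 7 cell classes, 35 fixed lists gave 216 tests, of which camera called 27 higher and 58 lower. With an estimated correlation or with fry none of the 85 calls passed the adjusted threshold; the lowest adjusted p values were 0.395 and 0.115, and 16 and 27 of the calls had an unadjusted p under 0.05. The treated mice lay wholly apart from the vehicle mice in 33 of the 85, and 41 held without each mouse in turn. The real grouping gave the smallest p of the 10 splits of the mice for 30 of the 85 calls. Ribosomal protein genes and oxidative phosphorylation were lower in 7 of 7 classes; ribosomal protein reads are shared with pseudogenes, so single members are uncertain. For the ribosomal list another split of the mice gave a smaller p in all 7 classes. Mitochondrially encoded genes were higher in 6 of 7 classes and immediate early genes, which tissue dissociation can also induce, in 4 of 7. Mitotic genes were lower in 5 of 6 classes, Myc targets in 5 of 7, S-phase genes and cholesterol synthesis in 4 of 6, and NF-kB cytokines, MHC class II and antigen-presenting fibroblast genes in 3 of 7. Lysosome genes were higher in 3 of 7 classes, T cell exhaustion and naive T cell genes in 3 of 6, and autophagy genes in 2 of 7. MAPK output was lower in 2 of 6 classes, the extracellular matrix and neutrophil maturation lists in 3 of 6, and the integrated stress response in 2 of 7. Neutrophil maturation was not called in neutrophils, nor the extracellular matrix and antigen-presenting fibroblast lists in fibroblasts. Their calls therefore do not show that these programmes fell in their own cells. The 2 T cell lists, by contrast, were called in T and NK lymphocytes.

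The remaining lists were called in at most 1 class each way, apart from the myofibroblastic fibroblast list, which was lower in 2 and higher in 1 of 5 classes. The myofibroblastic list was not called in fibroblasts. MHC class I was higher in 1 and lower in 1 of 7 classes, and classically activated macrophage genes were higher in 1 and lower in 1 of 6. In macrophages the classically activated list was not called, while the alternatively activated list was. The alternatively activated macrophage and p53 lists were higher in 1 of 6 classes each, and glycolysis and hypoxia in 1 of 7. The classical tumour programme was lower in 1 of 5 classes, endothelial adhesion in 1 of 6 and the mesenchymal tumour programme in 1 of 7. Each of these calls was in macrophages, not in tumour or endothelial cells. No class was called for T cell cytotoxicity, acinar secretory, inflammatory fibroblast or receptor tyrosine kinase genes (0 of 5 each), angiogenic endothelial genes (0 of 4), or mature dendritic cell and type I interferon genes (0 of 6 each) by camera. The haemoglobin and sex-linked lists had too few genes to test.

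A test of the difference itself asked whether tumour cells responded unlike fibroblasts or macrophages of the same mice. It found 0 of 15379 genes with a different response between tumour cells and fibroblasts and 0 of 15457 between tumour cells and macrophages in edgeR, with 1204 and 1871 at an unadjusted p under 0.05; DESeq2 called 159 and 315. Simulated 4-fold differences were recovered in 0% of genes against fibroblasts and 24.9% against macrophages, so differences of that size were mostly not detectable. Closest to the threshold were Meis1, a homeobox factor, at 4.29 in tumour cells and 0.30 in fibroblasts (difference 4.06 ± 0.33 SE, adjusted p = 0.0619), and Trim29 at −2.88 in tumour cells and 3.22 in macrophages (difference −6.18 ± 0.63, adjusted p = 0.124). Against fibroblasts the rule also named Ppp2r2b, Gstt2, Prxl2a, Il1a, Abi3bp, Ldhb and Hcn4, with adjusted p from 0.396 to 0.479. Against macrophages it named Meg3, Phyhd1, Auts2, Edil3, Rian, Stmn1 and Ddah2, each with adjusted p = 0.233; Stmn1, a microtubule regulator of dividing cells, stood at 0.54 in tumour cells and −1.66 in macrophages. Without treated 3, which leaves treated 1 and 2 as the treated group, the counts were 7 and 203 genes.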

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

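The splits of the mice, the test of tumour RNA as the whole difference in cell cycle genes, the order of the vehicle mice for those genes, the size of the ribosomal medians that was kept, and the range of ribosomal shares in cells of like UMI count were tests chosen only after the results were seen. Several groups of cells that took no class name were larger in a treated mouse than in any vehicle mouse. A group with leading genes of erythroid precursors and basophils together held 70 cells of treated 2 (1.36%), against 2 in the highest vehicle mouse. Unnamed cells in 4 sub-clusters with Lypd8, a gene of intestinal epithelium, among the leading genes numbered 104 in treated 3 and at most 1 in a vehicle mouse; of these, 29 were led by Spink4 and Muc2 and another 29 lay in sub-clusters of under 20 cells. The naming was uneven here, since a sub-cluster led by Lgals4, Rbp2 and Alpi, also genes of that epithelium, was kept as tumour cells with 189 cells of vehicle 1. Cells led by tumour and macrophage genes together numbered 13 in treated 1 and 0 in vehicle mice. Cells of low UMI count without epithelial markers among their leading genes numbered 240 in treated 2 (4.66%), against 1 in the highest vehicle mouse. Cells with fewer than 3 markers of any type numbered 159 in treated 2 (3.09%), against at most 2. Other unnamed groups went the other way: cells with more leading markers of plasmacytoid dendritic than of tumour cells numbered 149 in vehicle 2 and at most 3 in a treated mouse, and cells with more leading markers of conventional dendritic cells than of macrophages numbered 79 and 61 in vehicle 2 and 3 and at most 18 in a treated mouse. By marker score the plasmacytoid and conventional dendritic groups ranked first as tumour cells and as macrophages, and the rule on leading genes left them unnamed. The unnamed share differed between mice, and all unnamed groups were left out of every test.

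Camera called ribosomal protein genes lower with treatment in 7 of 7 classes, and in 0 of 7 with an estimated correlation. Their share of UMIs in tumour cells was 16.1% to 18.9% in treated mice and 26.9%, 17.6% and 29.7% in vehicle 1, 2 and 3, an overlap also found in fibroblasts and in T and NK lymphocytes; in the other 4 classes every treated mouse lay below every vehicle mouse. In all 7 classes another split of the mice gave a smaller p for this list. At the preset correlation camera called 61 to 78 lists in each of the other splits, so a small p is not particular to the groups. The calls therefore decide nothing, although camera still called the list lower in 6 of 7 classes without vehicle 1, in 7 of 7 among cells with at most 10% mitochondrial UMIs and in 7 of 7 with treated 1 and 2 summed. Among cells with at most 10% mitochondrial UMIs the median kept at least 50% of its size in 7 of 7 classes (96.3% at the least). The few cells over that cut were therefore not most of the difference. The cut left 1695 of 1803 tumour cells in treated 1, 641 of 814 in treated 3 and 47 of 47 endothelial cells in vehicle 1. Damage in cells under the cut was not tested, so damaged cells stay open. The other barcode set of vehicle 1 stays open: without it 4 of 7 classes kept at least 50% of the median, between the bounds set. The median then went from −1.44 to −0.30 in neutrophils, from −0.53 to −0.18 in macrophages and from −0.55 to −0.35 in fibroblasts. It went from −0.32 to −0.18 in B lymphocytes and from −0.33 to −0.11 in T and NK lymphocytes, where the call was lost. The likeness of treated 1 and 2 stays open too. Among cells of 4000 to 8000 UMIs the difference in share kept 123%, 122% and 152% of its size in fibroblasts, macrophages and tumour cells, and in these 3 of 3 classes every treated mouse lay below every vehicle mouse. This argues against the UMI count of a cell by itself as the source there. That range took a different part of each library. It held 38 of 814 tumour cells in treated 3 and 97 of 805 macrophages in treated 1, against 824 of 1581 macrophages in vehicle 2. Other differences between the libraries, such as depth, therefore stay open. For the other 4 classes the UMI count of a cell stays open too, because too few cells of some mice lay in that range. Vehicle 1 held 9 endothelial cells there. Endothelial shares there were 12.2%, 10.8% and 11.1% in treated 1, 2 and 3 and 14.8% and 19.6% in vehicle 2 and 3. Neutrophil shares there overlapped, at 6.64% and 2.55% in treated 1 and 3 and 6.26% and 5.92% in vehicle 1 and 3. The bound of 5 classes set for the whole pattern could not have been met. An effect of the drugs may also account for it and was not tested apart from the groups.

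Camera called S-phase and mitotic genes lower in fibroblasts, macrophages and endothelial cells, in 6 of 6 pairs of class and list, and in 0 with an estimated correlation. Another split of the mice gave a smaller camera p for both lists in fibroblasts, S-phase genes in macrophages and mitotic genes in endothelial cells. Those calls therefore do not tie the pattern to the groups. The real split gave the smallest p for mitotic genes in macrophages and S-phase genes in endothelial cells. The S-phase call in macrophages was lost without treated 3 (−0.19, adjusted p = 0.123). Vehicle 1 had the lowest sum of the vehicle mice in 3 of 3 classes (304, 1011 and 543 CPM), which argues against its barcode set as what raised the vehicle group. That 6 of 6 pairs of class and list were called lower without it adds nothing, since leaving out the lowest vehicle mouse leaves the higher 2. At the mean cell cycle level of tumour cells, tumour RNA carried at most 9.13% of the difference between the groups. This argues against free tumour RNA of that make-up as the whole difference. Doublets with dividing tumour cells would carry more than that mean, so the value cannot exclude them. Free RNA stays open as a part of the difference, because tumour RNA could carry up to 36.7% of cell cycle counts in 1 vehicle mouse. That value lay between the bounds set. A response of dividing stromal cells to treatment is a biological explanation the design names, and it was not tested apart from these.

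The endothelial count fell from 152 genes to 2 with treated 1 and 2 summed. That these libraries may be tissue of 1 animal could not be decided: 0 genes were on in one and off in the other, but other pairs of mice had 0 to 8, so the value cannot tell them apart. Their spread of log2 ratios was 0.197 in endothelial cells, near the sampling value of 0.159, and 0.12 in tumour cells, above the sampling value of 0.0285. If they were 1 animal, the treated group would hold 2 mice. No biological explanation of the likeness was tested.

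The 10 splits of 6 mice are too few for a share under 0.05. Only the real split gave as many genes in endothelial cells (1 of 10; 152, with 3 as the highest of the others), in T and NK lymphocytes (1 of 10; 7, highest other 3) and over the gene lists (1 of 10; 85 calls, highest other 78). All 10 gave as many as the real 0 in B lymphocytes (highest other 0), fibroblasts (2), macrophages (1), neutrophils (1) and tumour cells (0), and as many as the real 0 differences in response between tumour cells and fibroblasts (9) or macrophages (6). For cell numbers 2 of 10 splits gave as many as the real 2 classes (highest other 3). The split with 9 genes put treated 1, treated 2 and vehicle 1 together, and the cause was not tested.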

How the results depend on the processing

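The summed, paired-removal and shared-cluster alternatives, and the mice left out of the tests of response differences, were tests chosen only after results were seen. Of 2102 alternatives for 132 single genes, 1699 kept direction and side of the threshold, 277 weakened, 57 strengthened, 68 moved and 1 reversed. Of 668 for 37 single lists, 567 kept both, 93 weakened, 3 strengthened, 4 moved and 1 reversed. Of 369 for counts and shares, 285 stayed close and 84 moved. The lowest sums of B lymphocytes and of T and NK lymphocytes held the fewest UMIs, 71195 and 70789. Simulated 4-fold changes were still recovered in 98.8% of the genes tested in each. In tumour cells and neutrophils the spread between mice left simulated 4-fold changes unrecovered. Unless a cause is named, the cause was not tested.

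With an estimated correlation 0 lists were called in each of the 7 classes, and with fry 0 in each. With DESeq2 the gene counts were 2 in B lymphocytes, 12 in T and NK lymphocytes, 320 in fibroblasts, 307 in macrophages, 2 in neutrophils and 447 in tumour cells, and 159 and 315 for differences in response from fibroblasts and macrophages. With no filter on low counts they were 42 in B, 73 in T and NK, 806 in endothelial cells, 84 in macrophages and 8 in neutrophils, with 1 and 1 response differences and 13 B, 19 T and NK and 20 endothelial lists. The free-RNA filter, which tests fewer genes, gave 0 T and NK and 282 endothelial genes, 5 T and NK and 6 tumour lists, and 1 and 1 response differences. With at least 50 cells per mouse, which leaves out vehicle 1, T and NK gave 30 and endothelial cells 821. With doublets kept they gave 4 and 64, 0 classes changed in cell number, and Cd74 in endothelial cells stood at 0.085 (adjusted p = 0.989, in a range of 0.017 to 0.116 over mice left out). With at most 10% mitochondrial UMIs macrophages gave 11 genes, and with at least 500 genes per cell their share differed by −0.164 points. TMM scaling of cell numbers left 1 class. With treated 1 and 2 summed, T and NK gave 4 and endothelial cells 2; without vehicle 1 and treated 2, B gave 10, T and NK 34 and macrophages 1 gene, and B 10 lists. Only tumour cluster 18 was shared by every mouse, with 28 cells in vehicle 1 and 1402 in vehicle 2. It gave 0 genes, and 3 single genes and 2 single lists moved under it.

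The numbers 1 to 3 showed no clear pairing of the mice. Correlations of residual expression were −0.113 to 0.232 (median 0.046) for the same number and −0.218 to 0.179 (median −0.034) for other numbers. Residuals were centred within groups of 3 mice, so this weak check cannot exclude a pairing. With the number as a block, endothelial cells gave 72 genes, macrophages 15, and cell numbers 1 class, islet cells (mesothelial adjusted p = 0.0791).

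Over the mice left out, genes changed ranged from 0 to 9 in B, 1 to 30 in T and NK, 2 to 821 in endothelial cells, 0 to 9 in fibroblasts and 0 to 2 in neutrophils, with 0 throughout in macrophages and tumour cells; response differences ranged from 0 to 7 and 0 to 203, and classes changed in number from 1 to 3. Lists ranged from 2 to 7 in B, 12 to 15 in T and NK, 13 to 17 in endothelial cells, 13 to 19 in fibroblasts, 13 to 18 in macrophages, 10 to 17 in neutrophils and 11 to 16 in tumour cells. The neutrophil MAPK output median ranged from −0.91 without vehicle 1 to 0.28 without vehicle 3. Differences in share (points) ranged from −3.59 to 0.561 for B, −0.0983 to 1.86 for T and NK, −1.22 to −0.611 for dendritic, 0.791 to 2.19 for endothelial, −2.98 to 1.64 for fibroblast, 0.350 to 1.04 for islet, −2.53 to 8.52 for macrophage, 0.373 to 0.630 for mesothelial, −14.9 to −6.85 for neutrophil and −4.51 to 12.7 for tumour cells.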

Other observations

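The values below come from planned tests, apart from the neutrophil sub-clusters and the share in a UMI range, which were looked at after results were seen. Il1b, which myeloid cells make on activation, was abundant in neutrophils and macrophages of both groups. In neutrophils it stood at 10955 ± 3001 CPM in treated and 10811 ± 7804 CPM in vehicle mice (SD, n = 3; log2 fold change 0.02, edgeR adjusted p = 0.998), and in macrophages at 1610 ± 585 and 1453 ± 1053 CPM (0.15, adjusted p = 0.971). The chemokine Cxcl2 stood at 3287 ± 796 and 3401 ± 2050 CPM in macrophages (−0.05, adjusted p = 0.985) and at −0.73 in neutrophils (adjusted p = 0.872). In endothelial cells, where Il1b was far scarcer, it fell from 29.6 ± 26.3 to 4.49 ± 1.99 CPM (−3.00, adjusted p = 0.0289). That call was lost without treated 1, treated 2, treated 3 or vehicle 3, and the highest adjusted p over the mice left out was 0.119. It was also lost with doublets kept (−1.60, adjusted p = 0.506). Il1b in endothelial cells was among the genes removed by the filter on genes under 10% of their level in another class.

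Rarer cell classes had too few mice with 20 cells for a gene test, and the cell numbers of the 3 classes below did not pass in edgeR. Acinar cells, which secrete digestive enzymes, numbered 26, 33 and 3 in treated 1, 2 and 3 and 0, 0 and 210 in vehicle 1, 2 and 3. Plasma cells, which secrete antibodies, numbered 2, 4 and 72 in treated mice and 41, 48 and 18 in vehicle mice. Pericytes and smooth muscle cells numbered 26, 23 and 31 in treated mice and 14, 59 and 18 in vehicle mice. Ribosomal protein genes took 28.9% ± 0.284 of B lymphocyte UMIs in treated and 35.8% ± 4.99 in vehicle mice. In neutrophils the share was 18.1% in vehicle 1, 6.27% in vehicle 2 and 5.22% in vehicle 3, against 4.78% ± 0.46 in treated mice. A neutrophil sub-cluster led by Elane, Ctsg, Prtn3 and Mpo had 25 of its 27 cells in vehicle 1 and a median of 32374 UMIs. Another, led by Ngp and Camp, had 98 of 114 there and a median of 6418. Cells of high UMI count weigh more in a summed share, and the share per sub-cluster was not tested. Among vehicle 1 neutrophils in the UMI range used above the share was 6.3%.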
